A study of Mus musculus with 26 samples.

How the data were processed

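Samples were grouped by the labels: iPSC clones (n = 5), tail-tip fibroblasts (n = 5), ESC lines D3 and R1 (n = 3 each), activin-treated iPSC clones 2 and 3 (n = 2 each), islets (n = 3) and hepatocytes (n = 3). Per the labels' protocols, 5 ng of total RNA entered each reverse transcription, PCR ran for 40 cycles, 303 miRNAs were assayed, and Ct values were normalized to the U6 small nuclear RNA RNU6. The activin concentration is given as 100 ng/ml in the treatment protocol, for 5 days, and as 100 ng/ul in the sample characteristics. Software and threshold settings for the Ct values are not given in the sources used here.

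The deposited Ct table holds raw threshold cycles, in PCR cycles, for 315 assay positions on 4 lettered plates, A to D, in 26 samples. Its rows carry positions and no miRNA names, and the reference tables at hand could not pair them with names. Lists of miRNA families and cell type markers, fixed before the data were examined, were therefore not tested. No row is labelled RNU6, and whether an unnamed row holds it cannot be told. The labels give 303 miRNAs, fewer than the 315 positions, and all positions were treated as miRNA assays. Of 8190 values, 950 (11.6%) have no Ct. In 90 of these the group's median Ct was below 30, so an empty value is not always a low level. Another 75 values are exactly 36, and whether these were measured or filled in is not known. The precision of a Ct depends on its level, and no technical replicates were used here.

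The authors' deposited fold-change table is on a log2 scale, as differences in normalized Ct. Per the file headers it gives 2 to the power of minus the difference, but its values equal the mean normalized Ct of the first-named group minus that of the second, over the samples with a Ct. A positive value thus means less RNA in the first-named group. The table holds iPSC against fibroblasts (296 values, 213 of them positive), islets against hepatocytes (286) and untreated against activin-treated iPSC (303, of which 268 are positive).

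These values fix the reference Ct that was subtracted in each sample, up to a constant. Least squares on the Ct table and the authors' values recovered it for 20 samples, separately for positions A and B, for C and for D, with a largest residual of 4.0e-09 cycles. The recovered values are called RNU6, since the labels name that reference. The recovery was tested on simulated data first. For ESC no such values could be recovered. Fold changes below are positive when the first-named group has more RNA.

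The plan set before the data were examined used RNU6 for every comparison. It was kept for iPSC against fibroblasts, activin-treated against untreated iPSC, the difference between clones, and hepatocytes against islets. For the comparisons with ESC it was replaced by the mean Ct of the assays with a Ct below 35 in all 26 samples, taken per position set (87 for A and B, 26 for C, 9 for D). That reference was also run as an alternative for the other comparisons.

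Log2 relative expression was the reference Ct minus the assay Ct. Values above 35 or without a Ct were set to 35, so that the size of a fold change against a group with no sample below 35 depends on that limit. An assay was tested when at least 50% of the samples of either group had a Ct below 35. Group means were fitted by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in a fit shared by all groups with the reference (20 samples with RNU6, 26 with the mean Ct). The 2 treated samples of a clone were averaged first, leaving 18 and 24 columns. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The clone difference was fitted on unaveraged samples. Assays were named by a rule set beforehand, the 10 largest rises and falls among those called and detected in all samples of the higher group, shortened to 2 each because positions are not miRNA names. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

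Replicate numbers were checked for pairing by correlating the deviations of same-numbered samples from their group means. The correlations ranged from -0.056 to 0.328 for iPSC and fibroblasts and from -0.052 to 0.189 for hepatocytes and islets, so the numbers were not taken to pair samples. Treated and untreated iPSC are paired by clone in the labels, and that block is among the alternatives.

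The fit was tested on simulated data with the spread of the real groups, 60 changed assays per run and 10 runs per comparison. Of assays changed 16-fold, it recovered 24.2% for iPSC against fibroblasts relative to RNU6 and 76.0% relative to the mean Ct. The share was 16.8% and 54.5% for hepatocytes against islets, 71.7% for iPSC against ESC, 72.9% for ESC against fibroblasts and 51.3% for D3 against R1. For activin it was 0.510% relative to RNU6 and 56.7% relative to the mean Ct. Of assays changed 4-fold, 26.8% were recovered for iPSC against ESC. At most 1.02% of unchanged assays were called in any of these.

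Alternatives set beforehand were the other reference, quantile normalization, limits of 40 and 32, missing values in place of the limit, other filters, a fit on the compared groups alone, trended and robust eBayes, a 2-fold minimum, the replicate block, each line or clone alone, and leaving out each sample. Added after seeing the data were the mean Ct over all position sets together, Ct below 15 as missing, and leaving out position set C, or C and D.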

Results

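MicroRNA levels were profiled in mouse cells by stem-loop RT-qPCR, in which a primer specific for the mature miRNA starts reverse transcription and a TaqMan probe reports the amplification. The value per assay is the threshold cycle (Ct), where a higher Ct means less RNA. The 26 samples comprised 5 clones of induced pluripotent stem cells (iPSC) made from tail-tip fibroblasts, 5 samples of those fibroblasts, and 3 samples each of the embryonic stem cell (ESC) lines D3 and R1. They also held 4 samples of iPSC treated for 5 days with activin A, a TGF-beta family ligand used to direct pluripotent cells towards endoderm, 2 from clone 2 and 2 from clone 3. Primary hepatocytes and pancreatic islets gave 3 samples each. Of 315 assay positions, between 187 and 276 had a Ct below 35 in a sample. The files name assays by position, not by miRNA, so positions such as B74 stand for the assays below. Apart from the iPSC, which are separate clones, the labels do not say whether samples of a group came from separate cultures or animals. P-values therefore measure the spread between these samples, which may be technical.

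**Figure D1:**
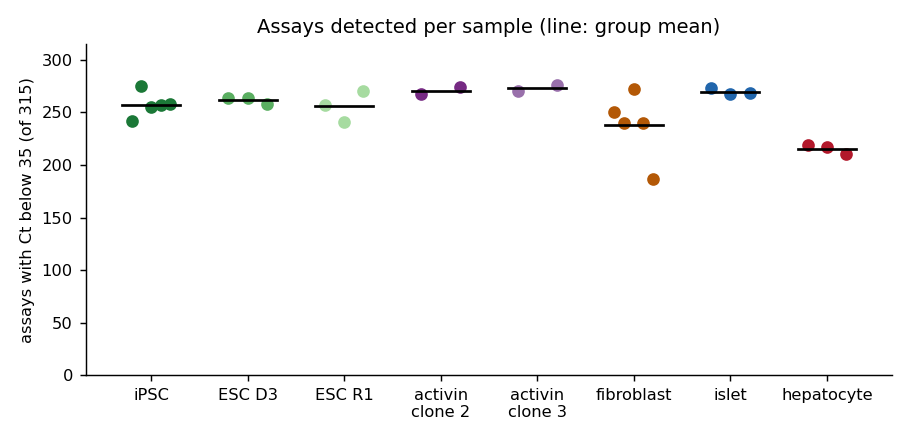
Number of assays with Ct below 35, out of 315, for each of the 26 samples by group, with a line at the group mean. The 3 hepatocyte samples have a mean of 215.3, the 3 islet samples lie between 267 and 273, and the fibroblasts range from 187 to 272.

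The comparison of iPSC with their parent fibroblasts addressed which miRNAs changed on reprogramming. Assay B74 was abundant in iPSC, with a Ct of 17.7 ± 0.968 (SD, n = 5), and had a Ct below 35 in 2 of 5 fibroblast samples, with a mean of 33.9 there. Assay B77 had a Ct of 18.3 ± 1.40 (SD, n = 5) in iPSC and reached a Ct, 33.7, in 1 of 5 fibroblast samples. Assays B13 and B14 went the other way. B14 had a Ct of 28.8 ± 1.48 (SD, n = 5) in iPSC and 21.6 ± 2.89 (SD, n = 5) in fibroblasts, and B13 had 20.7 ± 3.39 (SD, n = 5) in fibroblasts and a Ct in 4 of 5 iPSC samples, with a mean of 26.3. Across the panel, 9 assays had a Ct below 35 in all 5 iPSC clones and in no fibroblast sample, and 0 assays showed the opposite. These counts use raw Ct. Fibroblast replicate 5 had 187 assays below 35, against 240 to 272 in the other fibroblast samples, which limits how many could be detected in all fibroblasts. The iPSC were also kept on feeder fibroblasts. Any feeder RNA in the iPSC samples would raise fibroblast assays there, and its share was not measured.

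Relative to RNU6, the small nuclear RNA that the authors used as the reference, the log2 fold change of iPSC over fibroblasts was 15.10 for B74 (SE 1.15, limma adjusted p 2.27e-08) and 14.62 for B77 (SE 1.20, adjusted p 4.03e-08). It was -9.18 for B13 (SE 1.56, adjusted p 0.000144) and -8.95 for B14 (SE 1.15, adjusted p 8.98e-06). Relative to the mean Ct of the assays detected in all 26 samples, the reference used for ESC below, the values were 18.08 for B74, 17.61 for B77, -6.19 for B13 and -5.96 for B14. With most fibroblast samples at the limit of 35, the size of the rises depended on that limit. Relative to RNU6, B74 was at 12.54 and B77 at 11.88 with the limit at 32, and at 18.10 and 18.62 with the limit at 40. In the authors' deposited table, where a positive value means less RNA in the first-named group, B14 stands at 8.95, B13 at 7.58 and B74 at -17.01. The latter values are means over the samples with a Ct, whereas samples without one were set to 35 here. Without iPSC replicate 4, which had no Ct at B13, the log2 fold change of B13 was -7.58. Of 271 assays tested, 116 passed the threshold of 0.05, 20 higher and 96 lower in iPSC. Requiring a Ct below 35 in every sample left fewer assays and gave 77 calls, 5 of them higher, while the settings run called between 5 and 91 assays higher. With the mean Ct as the reference, 91 were called higher and 55 lower, and the median log2 fold change moved from -1.85 to 0.67. With quantile normalization 62 were higher and 75 lower. The sign differed between the references for 87 of 271 assays. Within a position set, changing the reference shifts all fold changes by a constant, so calls under both are not independent evidence. Called under both were 20 assays higher in iPSC and 55 lower, with 0 called in opposite directions. The 20 were all those called higher relative to RNU6, and the 55 all those called lower relative to the mean Ct. These 75 in all became 45 with a Ct below 35 required in every sample. The 20 higher ones had a median log2 fold change of 4.56 relative to RNU6 and 7.28 relative to the mean Ct. For the 55 lower ones these medians were -6.68 and -3.73.

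In position set A and B, which shared a reference, RNU6 Ct in iPSC minus fibroblasts was -1.80 cycles, while the mean miRNA Ct differed by 1.18 cycles. Leaving out each sample in turn, RNU6 lay between -2.62 (without fibroblast replicate 3) and -1.19 (without fibroblast replicate 2) there, and the mean miRNA Ct between 0.40 and 2.07 (without fibroblast replicates 3 and 5). In set C the values were -1.59 and 0.96 cycles, with ranges of -2.53 to -0.99 and 0.46 to 1.88 without the same fibroblast replicates, 3 and 5. In set D, at 0.31 and 0.53 cycles, no direction held. RNU6 there was -0.16 without iPSC replicate 1, -0.02 without fibroblast replicate 1 and 1.36 without fibroblast replicate 5. Without fibroblast replicate 3 both turned, to -0.62 and -0.41. Without fibroblast replicate 3, and likewise without fibroblast replicate 5, 13 assays were called higher relative to RNU6 in place of 20.

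**Figure D2:**
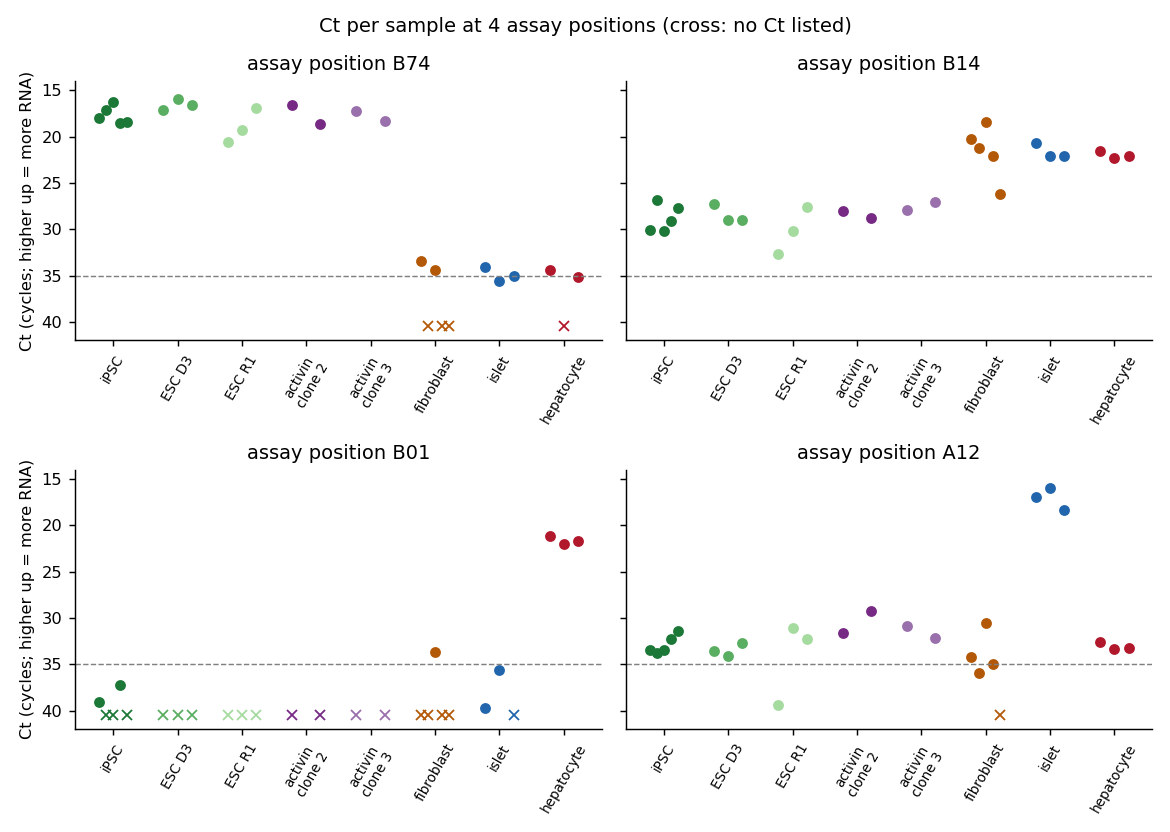
Ct of each of the 26 samples (y axis in cycles, inverted so that more RNA is higher) at assay positions B74, B14, B01 and A12, by group. Crosses below the axis of measured values mark samples with no Ct listed and the dashed line is the limit of 35; B74 lies at a mean of 17.7 in iPSC, B01 at 21.6 in hepatocytes and A12 at 17.1 in islets.

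ESC served as the pluripotent reference for the same question. RNU6 of the ESC samples was not analysed here, so these comparisons used the mean Ct. B74 had a Ct of 17.8 ± 1.79 (SD, n = 6) in ESC and a log2 fold change over fibroblasts of 18.03 (SE 0.79, limma adjusted p 1.86e-13). B77 followed with 16.80 (SE 0.85). Lower than in fibroblasts were A44, at -7.23 (SE 1.46, adjusted p 0.000312), and B14, at -6.41 (SE 0.66, adjusted p 9.76e-08). A44 varied within ESC, where 4 of 6 samples had a Ct below 35, and its place ahead of B14 changed with the limit and with the samples left in. With missing values in place of the limit A44 was at -5.54 and B14 at -6.41. The values were -5.88 and -6.23 without replicate 3 of D3, which had no Ct at A44, and -6.67 and -6.91 without replicate 3 of R1. Of 276 assays, 85 were called higher and 53 lower in ESC, 57 and 65 with quantile normalization, and 83 in all when a Ct below 35 was required in every sample.

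On the same reference, iPSC and ESC shared 75 assays called higher and 49 called lower than in fibroblasts, among 269 tested in both, and 0 assays were called in opposite directions. Independent lists of these sizes would share 28.4 and 10.8. Both comparisons use the same fibroblast samples, and 100 simulations of unchanged groups gave a mean of 0.01 shared calls and at most 1. Those simulations called almost nothing in either comparison, on average 0.02 higher and 0.07 lower in iPSC, and 0.02 and 0.06 in ESC. A shared count that low was therefore certain beforehand, and it decides nothing about the observed overlap. Whether other cell types would share as many calls against these fibroblasts was not tested. The log2 fold changes correlated across assays with r = 0.965, against 0.524 in those simulations. Assays are not independent replicates. The covariance was 13.6, against 0.656 without effects, a difference of 13.0. With the fibroblasts split between the comparisons in 20 ways, the shared calls averaged 92.8, between 84 and 99, and r averaged 0.886.

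**Figure D3:**
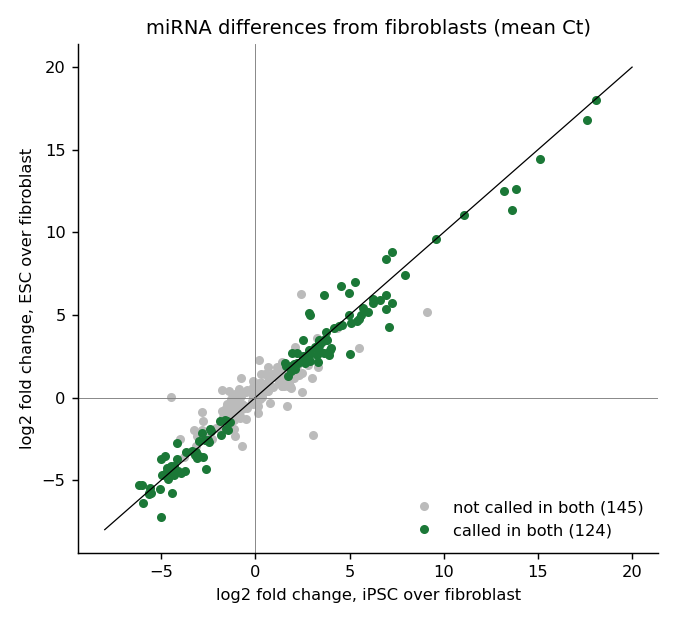
Each point is an assay tested in both comparisons (269), with its log2 fold change over fibroblasts in iPSC (x axis) and in ESC (y axis), both relative to the mean Ct; green points are the 75 called higher and 49 called lower in both and the line marks equal values. The shared fibroblast samples add to the correlation of 0.965, which averaged 0.886 with the fibroblasts split between the comparisons. Simulated groups without effects gave 0.524, which is not a share of the 0.965.

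Set directly against each other, iPSC and ESC were not separated by any assay past the threshold. Limma called 0 of 273 assays, the smallest adjusted p was 0.147, and 20 assays had an unadjusted p under 0.05. The median absolute log2 difference was 0.45. The 95% interval of the difference had a median half-width of 1.55, and it lay within 2 on the log2 scale, a 4-fold difference, for 114 of the 273 assays. For the other assays a difference of 4-fold or more was not excluded. Quantile normalization gave 2 calls, and a fit on these groups alone gave 1. Between the ESC lines D3 and R1, 0 of 273 assays were called, 3 had an unadjusted p under 0.05 (between 4 and 13 when each sample was left out in turn, the 13 without replicate 1 of R1), and the median absolute log2 difference was 0.55. The intervals there lay within 2 for 48 assays.

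Activin treatment addressed the first step of differentiation. The treated cells were grown without the feeder fibroblasts on which the untreated iPSC were kept, so that treatment and feeder removal went together. B74 stayed abundant, with Ct values between 16.6 and 18.6 in the 4 treated samples. The smallest p was at C61, named after its values were seen, with a Ct of 30.7 ± 1.77 (SD, n = 5) in untreated iPSC and 24.2 ± 2.26 (SD, n = 4 samples of 2 clones) in treated cells. Every treated sample of C61 lay below every untreated clone in Ct, the highest treated value being 27.3 and the lowest untreated 29.4. Relative to the mean Ct, its log2 fold change was 5.07 (SE 1.10, limma adjusted p 0.0469) and C61 was the only call among 284 assays, with 25 at an unadjusted p under 0.05. This call ended with the mean Ct over all position sets (adjusted p 0.104), without any 1 of the untreated clones (0.0542 to 0.114) and without replicate 2 of treated clone 2 (0.0736). Without replicate 1 of treated clone 3 the count was 5, and without replicate 1 of treated clone 2 it was 2. C61 lies in position set C, where the recovered RNU6 of replicate 1 of treated clone 3 was 8.22 cycles. In the other treated samples it was 0.38, -2.28 and -2.55. That high value raises the fold changes of treated cells relative to RNU6 in this set. Relative to RNU6 the log2 fold change of C61 was 8.62 (SE 1.98, limma adjusted p 0.0730), with 0 calls and 35 assays at an unadjusted p under 0.05. Of these 35, 34 were higher and 1 lower after treatment. The 35 became 16 without replicate 1 of treated clone 3, 71 without replicate 2 of treated clone 2 and 80 without replicate 2 of treated clone 3. The median log2 fold change of all assays was 1.68 relative to RNU6 and -0.11 relative to the mean Ct. Between the means of the 4 treated samples and the 5 untreated clones, RNU6 Ct differed by 0.31 cycles in set A and B. It differed by 2.11 cycles in set C and by -1.34 in set D. The mean miRNA Ct differed by -1.21, -1.44 and -1.64 cycles in these sets, so the rise relative to RNU6 was also present in set A and B. With clones as the replicate (n = 2), the 95% interval had a median half-width of 3.47 relative to RNU6. Without replicate 2 of treated clone 3, 4 assays were called.

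For the difference between the responses of the clones, the fit called 1 of 284 assays, B95. In clone 2, B95 had a Ct of 22.1 before treatment and no Ct in either treated sample. In clone 3 the Ct was 22.9 before and 22.1 and 20.3 after treatment. The log2 difference of the responses, clone 3 minus clone 2, was 14.48 (SE 2.96, limma adjusted p 0.0423), with the samples lacking a Ct set to the limit of 35. Each clone had a single untreated sample, so the spread came from the treated duplicates and the other groups, and the call does not show that the clones differ beyond the variation between cultures. A fit on these samples alone, quantile normalization, a limit of 32 and missing values in place of the limit each gave 0 calls. Relative to the mean Ct 0 assays were called, and leaving out any of the 4 treated samples gave 0, 0, 3 or 10 calls, the 10 without replicate 2 of clone 3.

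Hepatocytes and islets were compared as cell types of endodermal origin. Assay A12 had a Ct of 17.1 ± 1.14 (SD, n = 3) in islets and 33.1 ± 0.378 (SD, n = 3) in hepatocytes. Assay B01 had a Ct of 21.6 ± 0.456 (SD, n = 3) in hepatocytes and below 35 in 0 of 3 islet samples. C94 was also lower in Ct in hepatocytes, 21.5 ± 0.749 against 26.5 ± 0.961 (SD, n = 3 each). B64 was detected in the 3 islet samples, but unevenly, with a Ct of 15.5 in replicate 1 and 28 in the other two. Hepatocytes had 215.3 ± 4.73 assays below Ct 35 (SD, n = 3) and islets 269.3 ± 3.21 (SD, n = 3). The two-sided exact permutation p of that difference was 0.1, the smallest that 3 against 3 samples allow. In all, 27 assays had a Ct below 35 in all islet samples and in no hepatocyte sample, and 1 assay, B01, the reverse.

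Relative to RNU6, the log2 fold change of hepatocytes over islets was -18.35 for A12 (SE 1.28, limma adjusted p 5.34e-09) and -13.16 for B64 (SE 3.07, adjusted p 0.00224). The fall of B64 was -9.62 without islet replicate 1. B64 lost its call with missing values in place of the limit (-11.06, adjusted p 0.128). The estimate was 10.98 for B01 (SE 1.48, adjusted p 1.92e-05), with every islet sample at the limit of 35, and 7.98 with the limit at 32. For C94 it was 6.10 (SE 1.64, adjusted p 0.00629). Relative to the mean Ct the values were -15.13 for A12, -9.94 for B64, 14.20 for B01 and 6.90 for C94. Of 276 assays, 121 were called, 4 higher and 117 lower in hepatocytes. A fit on these groups alone gave 69 calls, and a Ct below 35 required in every sample, which left fewer assays, gave 57. The settings run called between 2 and 37 assays higher in hepatocytes. Relative to the mean Ct 30 were called higher and 76 lower, and the median log2 fold change moved from -3.42 to -0.46. With quantile normalization 37 were higher and 46 lower. Relative to RNU6 the median was -2.20 without islet replicate 3. Here too the reference shifts all fold changes of a position set by a constant, so calls under both are not independent evidence. Called alike under both references were 4 higher and 69 lower assays, with 0 in opposite directions, and the 4 were all those called higher relative to RNU6. These 73 in all became 48 with the limit at 32, 47 with missing values in its place and 29 with a Ct below 35 required in every sample. The 69 had a median log2 fold change of -7.60 relative to RNU6 and -4.94 relative to the mean Ct. RNU6 Ct in hepatocytes minus islets was -2.38 cycles in set A and B, and -0.78 without islet replicate 3. In sets C and D, at 1.12 and -1.93, its sign turned without hepatocyte replicate 1, to -0.19 and 0.20. The mean miRNA Ct was higher in hepatocytes by 0.83, 1.92 and 2.09 cycles, and by 0.41 to 2.71 when each sample was left out in turn. Without islet replicate 3, 78 assays were called, and 8 and 9 were called higher without hepatocyte replicates 1 and 3. In the authors' deposited table for islets against hepatocytes, 230 of 286 values are negative, meaning more RNA in islets, with a median of -3.33.

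**Figure D4:**
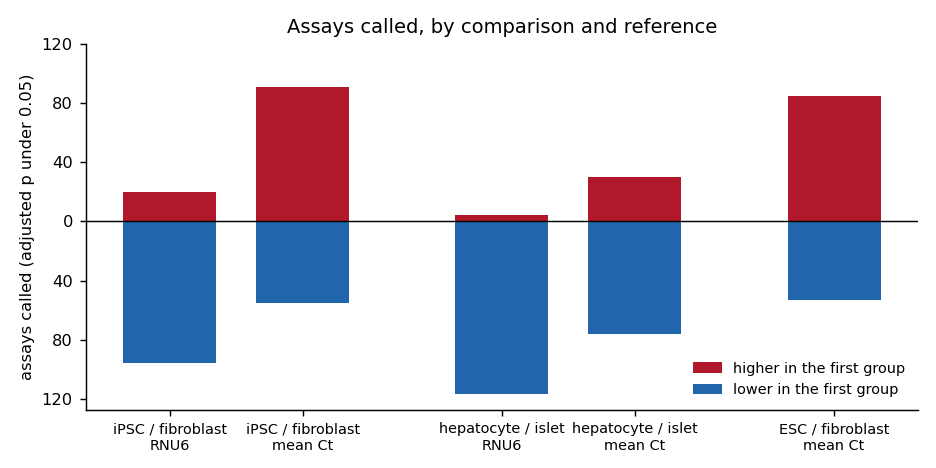
Number of assays called at an adjusted p under 0.05, higher (red, above the line at 0) or lower (blue, below it) in the first-named group, with RNU6 or the mean Ct as the reference. For iPSC over fibroblasts the counts are 20 and 96 with RNU6 and 91 and 55 with the mean Ct; for hepatocytes over islets they are 4 and 117, then 30 and 76, and for ESC over fibroblasts 85 and 53.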

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

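All tests in this part except the counts of sample splits, the test of the clone difference and the test of whether RNU6 tracked RNA input were chosen after the result was seen. Assay B77 had a Ct of 33.7 in fibroblast replicate 3, while the 4 other fibroblast samples had none and stood at the limit of 35, which set that sample apart from its group. With these fixed at 35, any Ct below 35 would stand apart, so the test decides nothing. The activin response of clone 3 minus that of clone 2 at B95 was 14.48 on the log2 scale, by a test of the difference itself. With 1 untreated sample per clone, and the treated samples of clone 2 set to 35, this does not show that the clones differ.

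Relative to RNU6, 82.8% of the assays called were lower in iPSC than in fibroblasts and 96.7% were lower in hepatocytes than in islets. Relative to the mean Ct these shares were 37.7% and 71.7%, and with quantile normalization 75 were lower against 62 higher and 46 lower against 37 higher. Relative to the mean Ct, 20.3% of the assays tested were still called lower in iPSC and 27.5% in hepatocytes, so the assays did not all shift alike. These are lower calls already counted in the results, and the large changes of single assays had made such an outcome certain. They do not decide whether a shift in RNU6 made most calls lower, since the share called lower changed with the reference. Whether RNU6 tracked RNA input was not settled. Subtracting it changed the pooled spread within groups by a factor of 0.984 (95% interval 0.918 to 1.06 over resampled assays). Assays of a sample share its RNU6 value within a position set, so that interval leaves out the spread between samples. The pooled factor joins opposite values. Subtracting RNU6 narrowed the spread in fibroblasts (0.649) and widened it in islets (1.86) and hepatocytes (2.14), with n = 3 for each tissue. A real difference in total miRNA between the cell types stays open and was not tested.

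In position set C, the recovered RNU6 of the first treated sample of clone 3 was 8.22 cycles, against 0.38, -2.28 and -2.55 in the other treated samples. In sets A and B and in set D, RNU6 of this sample was -0.16 and -0.10. Its mean miRNA Ct in that set lay 1.84 cycles below the highest of theirs (a difference of -1.84), which is consistent with a failed RNU6 reaction there and not with less RNA. The bound of this test was also reworded after its value was seen, since the first wording asked for a value within the range of the others and this value lay below it. C61 lies in this set, so its fold change relative to RNU6 carries that value; its change relative to the mean Ct does not. No biological explanation was tested.

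Hepatocyte replicate 1 held 11 of the 26 Ct values below 15. At 11 of these 11 assays both other hepatocyte samples lay over 5 cycles higher, with a median gap of 17.8 cycles and a smallest gap of 7.09. These values stayed in the main fit. Among the assays called higher in hepatocytes than in islets, C24 varied most, with a Ct of 18.4 ± 6.00 (SD, n = 3) in hepatocytes. Its limma adjusted p relative to RNU6 was 0.0420.

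Of 100 splits of the iPSC and fibroblast samples, 1, the real one, gave as many calls (116), and the highest other gave 40. Every other split mixes iPSC with fibroblasts, which widens the spread within groups, so the real one was likely to rank first. The other splits were a random draw of those possible, and samples of a group may be technical repeats. The count therefore does not exclude chance at the level of cultures or animals. The same held for ESC against fibroblasts, with 1 of 100, the real one having 85 higher and 53 lower calls and the highest other 111 calls. For iPSC against ESC and for D3 against R1 the real count was 0, which every split reaches (100 of 100 and 10 of 10), so the counts decide nothing there. For hepatocytes against islets 1 of 10 splits gave the real 121, with a highest other of 2, and 10 splits are too few for a share under 0.05.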

How the results depend on the processing

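The cause of the differences below was not tested, apart from settings that test fewer assays or samples. Counts are given with the percentage of assays tested. Requiring a Ct below 35 in every sample left fewer assays to test and gave 77 calls (50.7%) for iPSC against fibroblasts, 83 (53.2%) for ESC against fibroblasts, 57 (32.4%) for hepatocytes against islets, and 71 shared by iPSC and ESC. For hepatocytes against islets a fit on these groups alone gave 69 (25%). The replicate block gave 52 there (18.8%), 151 (55.7%) for iPSC against fibroblasts, 55.1% for ESC against fibroblasts, 2 (0.733%) for iPSC against ESC and 0 for D3 against R1. The numbers do not pair these samples. For iPSC against ESC, quantile normalization gave 2 (0.733%) and the compared groups alone 1 (0.366%). For activin, the count of 0 became 1 with the mean Ct (0.352%) and in clone 2 alone (0.352%), 2 with the limit at 32 (0.797%) or a Ct in every sample (1.01%), and 3 with quantile normalization (1.06%) or with Ct below 15 as missing (1.06%, added after seeing the data). With clone as the block it was 0, with 9 assays at an unadjusted p under 0.05 by limma. The single call between clones became 0 with the mean Ct per set or over all sets, quantile normalization, the limit at 32, missing values, a Ct in every sample and the compared groups alone, and 2 without a filter (0.635%). Leaving out each sample in turn called 32.1% to 41.0% for iPSC against fibroblasts, 44.6% to 56.7% for ESC against fibroblasts, 0 for iPSC against ESC and for D3 against R1, 0 to 1.44% for activin, 0 to 3.61% for the clone difference and 27.5% to 49.5% for hepatocytes against islets, with 111 to 139 shared calls. With quantile normalization 62 assays were called higher and 75 lower in iPSC than in fibroblasts, and 37 higher and 46 lower in hepatocytes than in islets. The count called alike under both references in hepatocytes and islets was 44 in the replicate block. B64 lost its call with missing values in place of the limit (-11.06), and C94 in the replicate block (6.10). B74, B77, B13, B14, A44, B01 and A12 kept direction and call in every setting in which they were tested. Not run were another small RNA control and the miRNA lists, since positions are unnamed, RNU6 for comparisons with ESC, and a block for the clone difference. One of the groups had no sample below 35 for 6 of 116 calls in iPSC against fibroblasts and 21 of 121 in hepatocytes against islets.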

Other observations

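Among the 9 assays detected in every iPSC clone and in no fibroblast sample, 8 were detected in all ESC samples, 8 in all activin-treated samples, and 5 in no islet or hepatocyte sample. Of the 27 assays detected in every islet and no hepatocyte sample, 14 were detected in all iPSC clones, 5 in all fibroblast samples, and 2 in no iPSC, ESC or fibroblast sample. Of the 20 assays called higher in iPSC than in fibroblasts under both references, 19 were also called higher in ESC, and of the 55 called lower, 49 were called lower in ESC. Part of that overlap may come from the shared fibroblast samples, which the 75 and 49 shared calls with ESC also carry; with a Ct required in every sample the shared calls were 71.

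Each mature cell type was also set against ESC, relative to the mean Ct. Hepatocytes had 61 assays higher and 102 lower, islets 63 and 64, and fibroblasts 53 and 85. Hepatocytes and islets shared 32 of the higher and 51 of the lower assays among 278 tested in both, where independent lists would share 12.3 and 23.5, and 4 were higher in hepatocytes but lower in islets and 10 the reverse; both use the same ESC samples, and no split of these was run. Of the shared ones, 21 of the higher and 41 of the lower were called the same way in fibroblasts. Group profiles over the assays detected in all samples correlated across assays at 0.967 for iPSC and D3, 0.969 for D3 and R1, 0.932 for iPSC and activin-treated iPSC, 0.544 for islets and hepatocytes, and 0.443 for iPSC and fibroblasts.

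The tests that follow were set before their results were seen, except those on neighbouring positions and the intervals of the set means, which were chosen afterwards. One hypothesis was that activin-treated cells lose miRNAs of pluripotent cells. The 85 assays higher in ESC than in fibroblasts had a median log2 fold change of -0.05 after treatment relative to the mean Ct (quartiles -0.65 and 0.40; fry p 0.932 for movement in 1 direction). A loss of feeder fibroblast RNA would lower the 53 assays higher in fibroblasts, whose median was -0.08 (fry p 0.793). A gain of endodermal miRNAs would raise the 31 assays higher in both hepatocytes and islets than in ESC, whose median was -0.09 (fry p 0.673). Relative to RNU6 the medians of these sets were 1.78, 1.62 and 1.63 (fry p 0.0685, 0.131 and 0.161), near the 1.68 of all assays. The bound set beforehand, a p of 0.05 or more, excludes none of these, since it names no size of change. The 95% intervals of the set means relative to the mean Ct were -0.75 to 0.84, -0.82 to 0.66 and -0.73 to 0.55. They leave smaller changes in the predicted direction open. A change shared by the assays that make up the mean Ct would cancel, so these intervals do not exclude a larger one. Relative to RNU6 the intervals were wider, -0.11 to 4.70, -0.51 to 4.06 and -0.67 to 4.37, and leave a gain of several cycles open. For assays in position set C they carry the RNU6 value of 8.22 cycles in replicate 1 of treated clone 3, which raises the fold changes. Relative to either reference the set means cannot be told apart from no change.

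Neighbouring positions tended to change alike. Of the 10 assays most raised in iPSC over fibroblasts, 7 lie at consecutive positions, and so do 7 of 10 in ESC. The longest runs were 2 among the 10 most lowered in each of these, 3 among the 10 most lowered in hepatocytes, and 1 among the 4 raised there. Across all assays tested, the fold changes of neighbours correlated at 0.445 in iPSC against fibroblasts and at 0.230 in hepatocytes against islets. Centred by plate letter these were 0.415 (permutation p 1.00e-04, the smallest that 10000 permuted orders can give) and 0.156 (p 0.00780). The deviations of replicates from their group means correlated between neighbours with medians of 0.024 and 0.014, the highest being 0.235, in fibroblast replicate 5, and 0.068. In iPSC against fibroblasts the fold changes exceeded that highest value by 0.180, or 2.55 SD of permuted orders, and correlated at 0.431 without that sample. The fold changes of neighbours thus correlated more than the deviations of any sample did. That SD measures a single correlation in permuted orders, not the error of a difference from the highest value. It therefore does not settle whether an effect of neighbouring wells that varies from sample to sample was present there. In hepatocytes against islets the excess was 0.0883, or 1.36 SD, under the 2 SD asked for, and such an effect cannot be told apart from a shared one. An effect common to all samples of a group would give the same 0.415 and stays open. A candidate explanation is that the panel's order places related miRNAs side by side, which was not tested because positions are unnamed.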
